A study of Homo sapiens with 6 samples.

How the data were processed

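RNA-seq of polyadenylated RNA was measured in 786-O cells, a human clear cell renal carcinoma line, in 3 samples labelled puro (the control) and 3 samples labelled shIGF2BP2, in which a short hairpin RNA targets IGF2BP2. The meaning of puro is not spelled out in the labels. IGF2BP2 encodes an RNA-binding protein that reads N6-methyladenosine (m6A), and the series title names an m6A-mediated TGF-beta-SMAD axis in clear cell renal carcinoma. RNA was isolated with RNAiso Plus and libraries were made with a TruSeq kit, per the labels' protocols.

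The deposited count table holds whole-number read counts per gene symbol, and the deposited FPKM table holds the same genes as FPKM, a value scaled by gene length and library total. Reads were trimmed with fastp 0.23.2, aligned to hg38 with STAR 2.7.10a and counted with featureCounts, and DESeq2 was also used, per the submitters' processing notes. The annotation release, the strand setting and the treatment of multimapping reads are not given in the sources used here. Reads from paralogs, overlapping genes and antisense partners therefore cannot be separated with certainty. The deposited FPKM values are the deposited counts rescaled: dividing one by the other gave the same gene length in every column for 16722 of 16722 genes with values in at least 2 columns, within a relative tolerance of 1e-06. The FPKM table thus adds a scaling and a gene length but no new measurement.

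Both tables hold 9 columns for the 6 samples. The puro columns carry 1 number, and the shIGF2BP2 columns carry 2. The last number was read as the replicate number, as in the puro columns. The number before it, 2 or 3, is explained by no label, and its columns are called set 2 and set 3 here. Each shIGF2BP2 sample thereby has 2 columns, whose counts were summed so that each sample entered the main comparison once. This summing was chosen when the column names were seen, before any comparison was run. The tables do not show that columns with the same last number belong together: deviations from the set means correlated across genes at -0.0942, 0.00408 and -0.0723 between set 2 and set 3 columns 1, 2 and 3, and columns of different sets correlated at 0.987 to 0.988 against 0.998 to 0.999 within a set. These values argue against the 2 columns of a sample being plain repeats of the same material. The main comparison therefore rests on the reading of the names alone. If the first number instead names the sample, only 2 knockdown samples exist, and that reading was fitted as an alternative. Set 2 and set 3 were also compared with puro separately and with each other in a fit of all 9 columns, chosen after the data were seen.

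Counts per column summed to between 33821216 and 47470019. The table lists 20020 genes, of which 2130 had no count in any column. Genes were filtered with filterByExpr, scaled by TMM factors, and tested with the edgeR quasi-likelihood test (edgeR 4.0.16, R 4.3.3), with p-values adjusted by Benjamini-Hochberg; genes under an FDR (false discovery rate) of 0.05 were called, with no minimum fold. The main comparison tested 13518 genes and the 9-column fit 13346. Values per gene are CPM, counts scaled to a common library total with TMM factors, as mean ± SD over 3 columns. Standard errors of fold changes were derived from the quasi-likelihood F statistic. The labels do not say whether samples came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

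Gene lists were tested with limma camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and again with an estimated correlation and with fry. The 29 lists, the main design, the rule for naming genes and most alternatives were fixed before the data were examined. Which lists are described at length was chosen afterwards. Genes named were IGF2BP2, IGF2BP1 and IGF2BP3; the 8 largest rises and 8 largest falls past the threshold with a mean of at least 5 CPM and no overlap between the groups; up to 2 rising and 2 falling members with the smallest FDR from each list described; 8 TGF-beta-SMAD genes; MYC, HMGA2 and CCND1 as proposed IGF2BP2 targets; and EPAS1 and VEGFA for the HIF pathway. Genes outside that rule are marked where they appear. Some genes that the rule names are not reported here, and counts over the named genes include them.

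Alternatives covered other scaling factors, filters on low values, DESeq2 1.42.0, limma-voom, limma on log2 FPKM with pseudocounts of 1 and 0.1, a gene length trend removed by loess, a replicate block, stricter thresholds, and each library left out in turn. Gene lists were tested with cameraPR on the fold change over its standard error for DESeq2, limma-voom and the length trend. On simulated counts with known changes, the main comparison recovered 29 of 50 changes of 1.25-fold, 35 of 50 of 1.5-fold, 41 of 50 of 2-fold and 49 of 50 of 4-fold among 13270 genes, with 7 false calls. For set 2 it recovered 23, 39, 43 and 45 of 50 at these sizes among 13051 genes with 8 false calls, and for set 3 it recovered 24, 31, 47 and 50 of 50 among 13040 genes with 9 false calls. Genes that the filter removed counted as not recovered.

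Words of 7 bases in 3' UTRs were related to fold changes across 12694 of 13317 genes tested in both fits, which were those with a 3' UTR of at least 50 bases in GENCODE 29 (GRCh38, the same assembly as hg38). Per gene, the log2 fold change, limited to ±2, was regressed on the presence of each word, with UTR length, GC content and expression as covariates. Words present in fewer than 100 genes were left out. On simulated fold changes for 12694 genes, a planted effect of -0.1 was estimated at -0.10 and one of -0.2 at -0.19, and in both cases the planted word ranked 1. This scan was designed after the fold changes had been seen. A site was defined as the leading word or its last 6 bases followed by A; a first run for the rises in both sets had used the word of second rank instead, and both definitions are reported. Fisher's exact test of the site was first run on the genes the word was picked on; it was replaced by shares in the part of the genes the word was not picked in, once all of these values had been seen. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1 were used. Confidence intervals of shares are exact binomial (Clopper-Pearson) at 95% and cover counting error only.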

Results

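The transcriptome of 786-O cells was measured in 3 control samples labelled puro and 3 samples with an shRNA against IGF2BP2. This line derives from a clear cell renal carcinoma and lacks functional VHL, so that HIF-2 alpha is constitutively active. The count table held 9 columns, 3 for puro and 6 for the knockdown, in 2 sets of 3 columns each. Depth ranged from 33821216 counts in puro replicate 2 to 47470019 in set 3 replicate 3. Log2 expression correlated at 0.998 to 0.999 across genes between columns of the same arm, and at 0.987 to 0.989 between columns of different arms, set 2 against set 3 included. Genes are not independent replicates, so these values only describe the libraries.

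The targeted gene was lower in every knockdown column. IGF2BP2 (chromosome 3, 185643739 to 185825056, minus strand, GRCh38) stood at 76.7 ± 2.05 CPM in puro (SD, n = 3), 23.9 ± 1.12 in set 2 and 33.7 ± 2.31 in set 3. Over all 6 samples its log2 fold change was -1.42 (SE 0.06, edgeR quasi-likelihood test, adjusted p = 2.03e-13). Set 2 retained 31.2% of the puro level and set 3 retained 43.9%, and this difference between the sets passed the same test (log2 0.49, adjusted p = 3.19e-06). The paralog IGF2BP3 had a log2 fold change of 0.14 (edgeR adjusted p = 0.0448), with 0.34 in set 2 and -0.06 in set 3. That call ended without puro replicate 1 (edgeR adjusted p = 0.175) and without each of the 3 shIGF2BP2 replicates (0.141, 0.0754 and 0.0814). Over all 24 alternatives its adjusted p ranged from 8.13e-05 to 0.551. IGF2BP1 was near the detection floor at 0.366 CPM on average and did not pass the test.

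**Figure D1:**
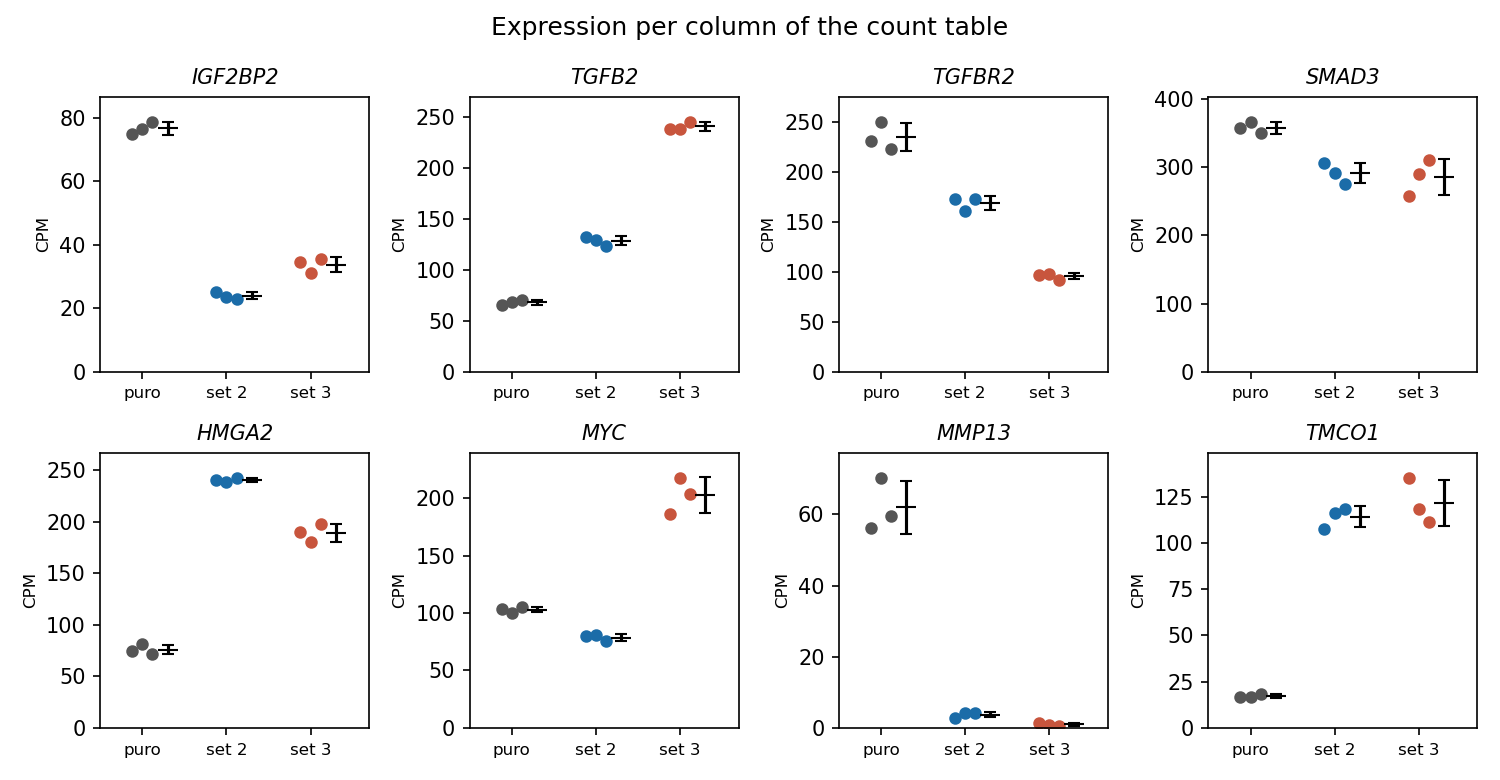
Expression of 8 genes in CPM (vertical axes, from 0) for puro, set 2 and set 3; each point is a column of the count table, and the bar beside the points gives mean ± SD (n = 3). IGF2BP2 was lower in both sets, while MYC lay below puro in set 2 and above it in set 3.

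The knockdown samples differed from puro in 7842 of 13518 tested genes (58.0%), 3896 higher and 3946 lower (edgeR quasi-likelihood test, FDR 0.05). Most of these differences were small, and 525 genes were higher and 486 lower by at least 2-fold. Set 2 alone differed from puro in 7989 genes and set 3 alone in 7425. Of these, 2003 genes were higher in both sets and 1862 lower in both, while 1204 moved in opposite directions. Lists of the same sizes drawn independently would share 1121 higher and 1102 lower genes. The sets also differed from each other in 8097 genes, about as many as either differed from puro. When the first number of the column names was read as the sample number, which leaves 2 knockdown samples, 1285 genes passed. All 1285 were also called in the main comparison with the same direction. That reading only regroups the same counts, so the shared direction is no separate evidence. Of the named genes 44 passed under that reading, against 71 in the main comparison. Those that no longer passed include IGF2BP3, TGFBR2, SMAD2, SMAD3, SMAD7, JUNB, MYC, CCND1, CXCL1, CXCL5, PFKFB3, MCM3, IGFBP3, EPAS1, VEGFA, MT-CYB, FTO and RPL19, with edgeR adjusted p values from 0.0516 for MT-CYB to 0.712 for VEGFA. The main comparison sums both sets within each sample, so the difference between the sets does not enter its p-values.

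Both sets were compared with the same 3 puro columns, which by itself makes their fold changes correlate. Pearson's r between the fold changes of the sets, across genes, was 0.474, against a mean of 0.519 in 20 simulations with no effect. The covariance was 0.239, against a mean of 0.0168 in the simulations, a difference of 0.222. At an unadjusted p under 0.05 by edgeR in both sets, 2188 genes were higher in both and 2063 lower in both, against at most 79 and 70 in the simulations; at FDR 0.05 the simulations gave at most 0 of each. The share of genes with the same sign in both sets was 64.3%, against a mean of 67.0% in the simulations. The simulations held only the spread between columns of the same arm, so a shift shared by all 3 puro columns was not covered. The 3 puro columns cannot be split further, so part of the shared calls may come from the shared controls.

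**Figure D2:**
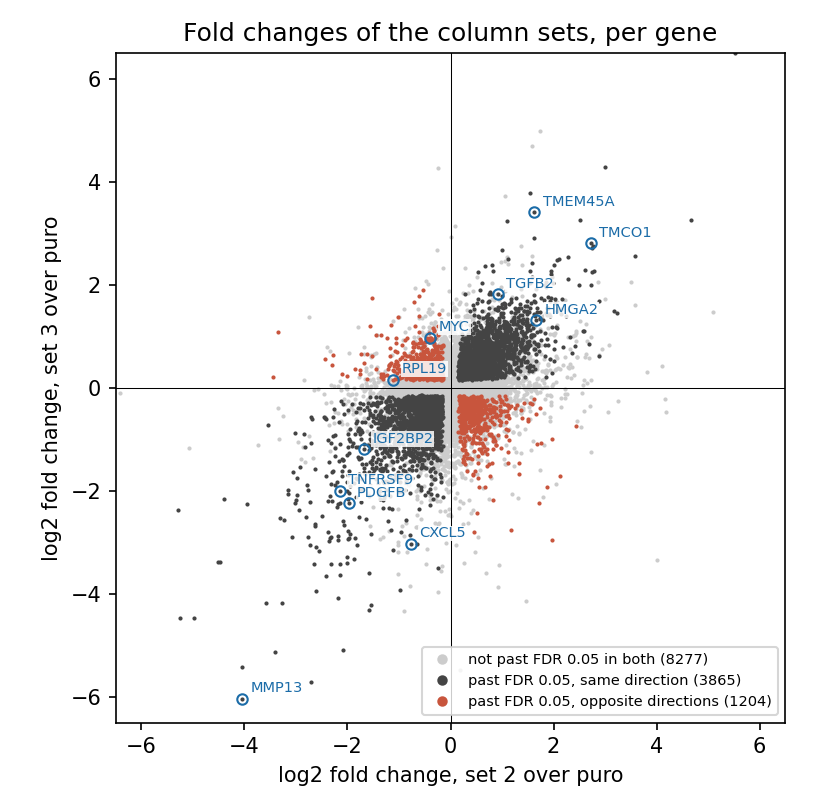
Log2 fold change over puro in set 2 (horizontal) and set 3 (vertical), 1 point per gene; 9 of 13346 genes lie outside the axes at ±6.5. Dark points passed FDR 0.05 in the same direction in both sets (3865), red points passed in opposite directions (1204), and blue circles mark named genes.

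Of the 8 largest rises, those of TMCO1, ARPC1A and PDE6D were close in size in both sets, and the other 5 differed between the sets by the edgeR test. TMCO1, an endoplasmic reticulum calcium channel (chromosome 1, 165724293 to 165827755, minus strand, GRCh38), rose by 2.72 in set 2 and 2.81 in set 3 on the log2 scale, from 17.3 ± 0.899 CPM in puro. ARPC1A, a subunit of the actin-nucleating Arp2/3 complex, rose by 2.76 and 2.75, and PDE6D, a chaperone of prenylated proteins, by 2.75 and 2.72. MEA1 rose by 2.51 in set 2 and 3.25 in set 3, CENPW, a kinetochore component, by 2.29 and 2.54, and ARL2BP by 2.11 and 2.51 (edgeR adjusted p of the differences 1.07e-09, 0.00576 and 0.00755). The imprinted, retrotransposon-derived gene PEG10 rose more in set 3 (3.23) than in set 2 (1.09), as did TMEM45A (3.42 against 1.63). Of these 8 genes, 7 (all but ARPC1A) hold the word ACACATC or CACATCA in the 3' UTR, as do 16.7% of 12510 searched genes outside the rises of at least 2-fold in both sets. The word was picked on the fold changes of all searched genes, these 8 included, so this share is no test of it. The shares given here are also not adjusted for UTR length. The 8 genes with the largest falls hold it in 0 cases, and 30 of all 244 falls of at least 2-fold in both sets do (12.3%, against 17.2% of others). Among the other named genes past the threshold, 7 of 25 that rose and 4 of 26 that fell hold it, TGFB2 and HMGA2 among the first and CA12 and PDGFB among the second.

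The deepest fall was that of MMP13, a collagenase (chromosome 11, 102942995 to 102955734, minus strand, GRCh38). It had a log2 fold change of -4.73 (SE 0.10), with -4.05 in set 2 and -6.03 in set 3. MAP7D2, a microtubule-associated protein, changed by -3.86, AFAP1L2, an adaptor of Src signalling, by -2.99, and ELF3, an epithelial transcription factor, by -2.88. ASB2 stood at -2.19 in set 2 and -4.09 in set 3, and BMF, a pro-apoptotic BH3-only protein, at -2.33 and -3.42 (edgeR adjusted p of the differences 5.17e-12 and 2.52e-08). VGF and KY changed by -2.66 and -2.60 over all samples. The difference between the sets also passed for MMP13, MAP7D2, ELF3 and KY but not for AFAP1L2 and VGF. Of these 8 falls, 4 hold GGGAAAT or GGAAATA in the 3' UTR (AFAP1L2, ELF3, BMF and VGF), words linked to lower values in set 3, and 1 (AFAP1L2) holds GTCATCA or TCATCAA, linked to lower values in set 2. Over all 244 falls of at least 2-fold in both sets, these shares were 27.9% and 17.2%, against 27.4% and 16.9% of 12450 others. All 16 of these largest changes were past FDR 0.05 in each set and in the same direction.

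Genes of the TGF-beta pathway moved in both directions. The ligand genes TGFB2 (log2 fold change 1.42) and TGFB1 (0.59) and INHBA (0.96), which encodes the activin A subunit, rose. The receptor TGFBR2 (-0.84), the latent TGF-beta binding protein LTBP1 (-1.48), the signal transducers SMAD2 (-0.28) and SMAD3 (-0.32) and the inhibitory SMAD7 (-0.48) fell. TGFBR1 (0.05) and SMAD4 (-0.08) did not pass the edgeR test, with adjusted p values of 0.586 and 0.289. TGFBR1 did pass in each set taken alone, but in opposite directions, set 3 lying above set 2 by 0.49. TGFB2 rose by 0.92 in set 2 and 1.82 in set 3, and TGFBR2 changed by -0.48 and -1.30 (edgeR adjusted p of the differences 1.35e-12 and 2.39e-11). The difference between the sets did not pass for LTBP1 (edgeR adjusted p = 0.317). With the first number of the column names read as the sample number, TGFBR2, SMAD2, SMAD3 and SMAD7 were no longer called (edgeR adjusted p = 0.0800, 0.216, 0.111 and 0.0687), and on log2 FPKM SMAD2 was not called either (limma adjusted p between 0.0760 and 0.0884). Of 43 tested ligands, receptors and SMADs, 13 rose and 16 fell (13 and 16 adjusted over the list alone), and the list as a whole was not shifted against other genes (camera adjusted p = 0.651).

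Among 40 genes induced by TGF-beta, 15 rose and 19 fell (15 and 19 adjusted over the list alone; camera adjusted p = 0.470). CCN2, a matricellular growth factor, rose by 1.95 and HMGA2, a chromatin architectural factor and proposed IGF2BP2 target, by 1.49. In set 2 and set 3, CCN2 rose by 1.11 and 2.50 and HMGA2 by 1.66 and 1.32 (edgeR adjusted p of the differences 3.49e-13 and 3.88e-05). PDGFB, a platelet-derived growth factor chain, and JUNB, an AP-1 subunit, had log2 fold changes of -2.12 and -1.25. That of JUNB was -2.17 in set 2 and -0.67 in set 3, and this difference passed the edgeR test (adjusted p = 2.08e-15). In set 2 taken alone, this list was shifted downwards (camera adjusted p = 0.0414, and adjusted p = 0.835 with an estimated correlation). The difference between the sets for this list did not pass (camera adjusted p = 0.121). Other proposed targets differed by set: MYC had a log2 fold change of 0.43 over all samples but -0.39 in set 2 and 0.97 in set 3, and CCND1 of 0.52, with 0.93 in set 2 and -0.02 in set 3.

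NF-kB targets and cytokines fell together. Of 33 tested members, 26 fell and 3 rose (26 and 3 adjusted over the list alone), with a median log2 fold change of -0.92 (camera adjusted p = 2.40e-07). With an estimated correlation the adjusted p = 0.0782 for all samples, 0.0301 for set 2 and 0.0165 for set 3. TNFRSF9, a T cell costimulatory receptor, had a log2 fold change of -2.08, and CXCL5, a neutrophil chemokine, of -1.50, with -0.77 in set 2 and -3.03 in set 3. CXCL1, a related chemokine, and CSF1, the macrophage colony-stimulating factor, rose by 0.50 and 0.43. Across the sets, 23 members were lower in both and 2 higher in both.

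4 other lists passed camera's test over all samples and were lost with an estimated correlation. For G1/S and DNA replication genes that estimate was 0.00878, under the preset 0.01, so a higher correlation is not what lost the call. For HIF targets, glycolysis genes and mitochondrially encoded mRNAs it was 0.0273, 0.0708 and 0.308. The NF-kB list also lost its call over all samples, with an estimate of -0.00244. A lost call therefore does not by itself show that a higher correlation was the reason, in these lists either. G1/S and DNA replication genes were lower, 33 of 50 falling and 8 rising (33 and 9 adjusted over the list alone; camera adjusted p = 0.00114, adjusted p = 0.228 with an estimated correlation). This list passed in set 2 (median -0.34, camera adjusted p = 0.000283, adjusted p = 0.277 with an estimated correlation) but not in set 3 (median -0.092, camera adjusted p = 0.141), and the sets differed (camera adjusted p = 0.00383, adjusted p = 0.513 with an estimated correlation). Its members included MCM3, a subunit of the replicative helicase (-0.62), and the repressor E2F8 (-1.43), while RPA2 and GINS2 rose by 0.73 and 0.82. Among glycolysis genes 19 of 26 fell and 3 rose (20 and 3 adjusted over the list alone; camera adjusted p = 0.00145, adjusted p = 0.522 with an estimated correlation), including the regulatory kinases PFKFB4 (-1.55) and PFKFB3 (-0.91). Glycolysis passed in set 2 (median -0.38, camera adjusted p = 0.000194, adjusted p = 0.277 with an estimated correlation) but not in set 3 (median -0.12, camera adjusted p = 0.109), the sets differed (camera adjusted p = 0.0499, adjusted p = 0.773 with an estimated correlation), and 8 members were lower in both. HIF targets showed 24 falls and 9 rises among 42 (24 and 9 adjusted over the list alone; camera adjusted p = 0.0169, adjusted p = 0.522 with an estimated correlation), with CA12 at -1.22 and IGFBP3 at -1.16. In set 2 and set 3, CA12 stood at -0.92 and -1.59 and IGFBP3 at -1.84 and -0.68. The call of the HIF list over all samples held in 24 of 27 alternatives. The HIF list passed in set 3 (camera adjusted p = 0.00172, adjusted p = 0.235 with an estimated correlation) but not in set 2 (camera adjusted p = 0.183), and the difference between the sets did not pass (camera adjusted p = 0.229). EPAS1, which encodes HIF-2 alpha, changed by -0.47. VEGFA was called at 0.16 over all samples, with 0.56 in set 2 and -0.39 in set 3, and lost the call when puro replicate 3 was left out (edgeR adjusted p = 0.0732, within a range of 1.51e-09 to 0.712 over 24 alternatives).

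Mitochondrially encoded mRNAs were higher. Of 13 tested, 11 rose by the edgeR test (11 adjusted over the list alone), with a median of 0.32 (camera adjusted p = 0.00178, adjusted p = 0.534 with an estimated correlation). MT-CYB and MT-ATP6 rose by 0.62 each, MT-CYB by 0.83 in set 2 and 0.39 in set 3 and MT-ATP6 by 0.64 and 0.63. These mRNAs took 2.26 to 2.40% of counts in puro, 3.13 to 3.29% in set 2 and 2.65 to 2.80% in set 3.

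Cytosolic ribosomal protein genes separated the sets. In set 2, 67 of 76 fell and 1 rose (69 and 1 adjusted over the list alone), with a median log2 fold change of -0.39 (camera adjusted p = 2.13e-08, adjusted p = 0.835 with an estimated correlation). In set 3, 60 rose and 1 fell (66 and 1 adjusted over the list alone), with a median of 0.26 (camera adjusted p = 2.46e-06, adjusted p = 0.777 with an estimated correlation). All 76 were higher in set 3 than in set 2 (median difference 0.67, camera adjusted p = 6.22e-17, adjusted p = 0.773 with an estimated correlation). RPL19 had log2 fold changes of -1.11 in set 2 and 0.16 in set 3. Summed over the sets the list did not shift (camera adjusted p = 0.585), with 6 members higher and 15 lower (3 and 11 adjusted over the list alone); without puro replicate 2 the median of cytosolic ribosomal proteins was -0.091 and passed (camera adjusted p = 0.0322). The directions in each set held under all 4 scalings run. Nuclear genes of oxidative phosphorylation also differed between the sets, 51 of 75 being higher and 5 lower in set 3 than in set 2 (median 0.30, camera adjusted p = 0.000502, adjusted p = 0.830 with an estimated correlation).

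**Figure D3:**
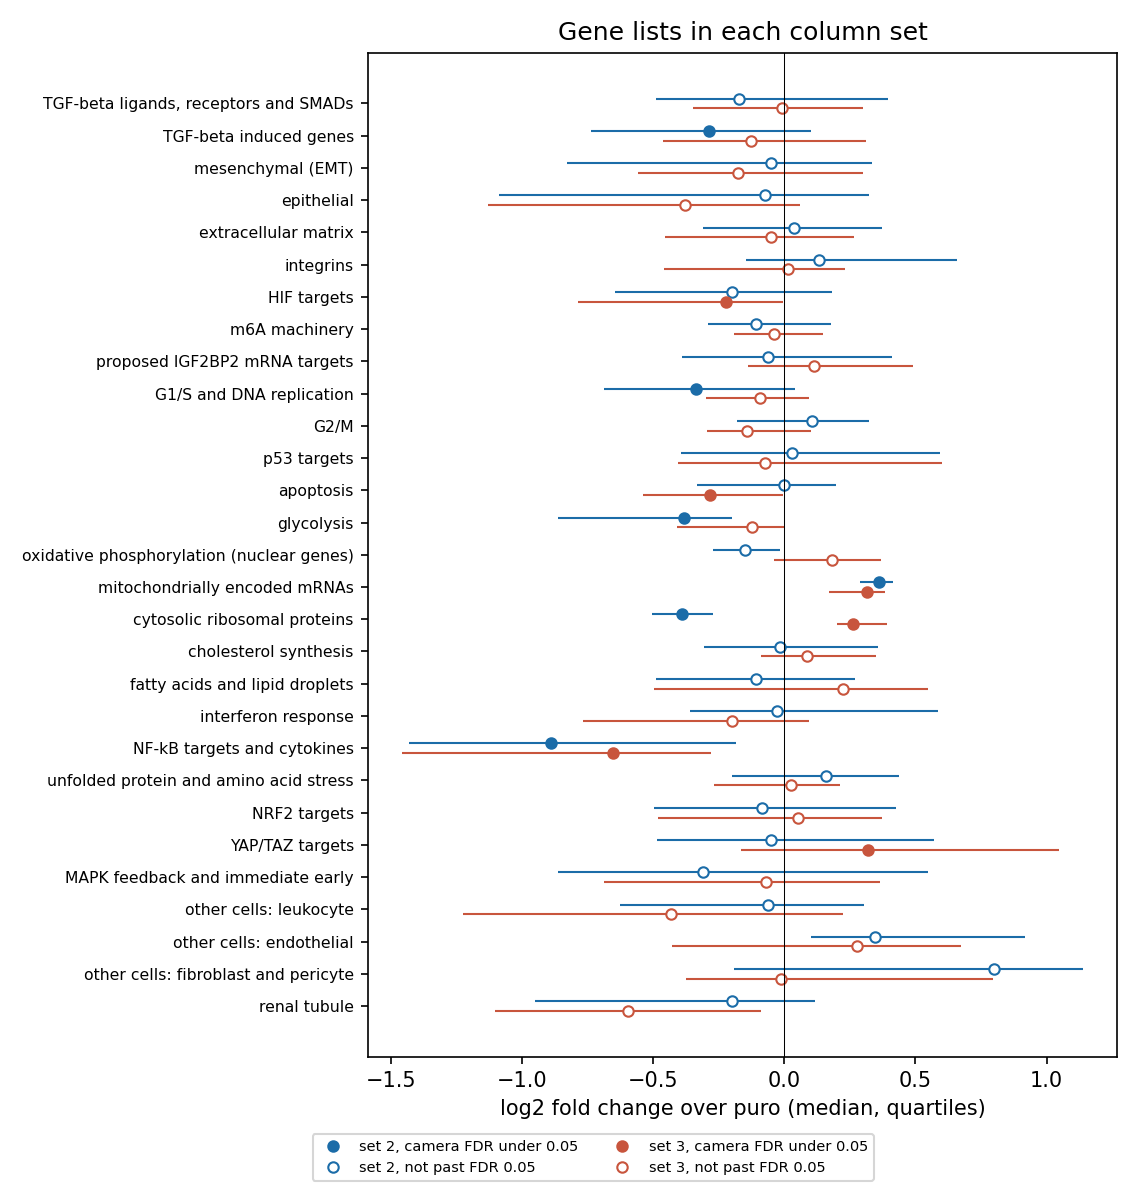
Median log2 fold change over puro of the tested members of 29 gene lists in set 2 (blue) and set 3 (red), with lines from the lower to the upper quartile; filled points passed camera's FDR of 0.05 with the preset correlation. NF-kB targets lay at -0.89 and -0.65, and ribosomal protein genes at -0.39 and 0.26.

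In the m6A machinery list, 7 of 28 genes rose and 9 fell (7 and 9 adjusted over the list alone; camera adjusted p = 0.548), the targeted IGF2BP2 being 1 of the falls. The E3 ligase CBLL1, a component of the writer complex, rose by 0.98 and the demethylase FTO by 0.60, and the methyltransferase METTL16 changed by -0.75. Extracellular matrix genes were split, 15 of 59 rising and 17 falling (15 and 17 adjusted over the list alone; camera adjusted p = 0.876), with COL13A1 at 1.65, LAMA5, a laminin chain, at -1.45 and TNC at -0.75. Of 37 apoptosis genes, 7 rose and 17 fell (7 and 17 adjusted over the list alone; camera adjusted p = 0.234), BOK rising by 1.51. In set 3 alone 20 apoptosis genes fell and 4 rose (21 and 5 adjusted over the list alone; median -0.28, camera adjusted p = 0.0147, adjusted p = 0.182 with an estimated correlation), while in set 2 10 fell and 10 rose (10 and 10 adjusted over the list alone; camera adjusted p = 0.940). The sets differed for this list (camera adjusted p = 0.0499, adjusted p = 0.513 with an estimated correlation).

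Markers of other cell types were mostly low. Among fibroblast and pericyte markers the highest was PDPN at 8.85 CPM, and among leukocyte markers SRGN at 31.9 CPM. Of the tested leukocyte, endothelial, and fibroblast and pericyte markers, 12, 10 and 10 genes, 2, 2 and 7 rose and 3, 1 and 1 fell, and none of these lists was shifted (camera adjusted p = 0.744, 0.640 and 0.189). PTPRC, the pan-leukocyte marker, averaged 0.0187 CPM. These 3 markers lie outside the rule for named genes and were picked after their values were seen.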

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

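The comparison of set 2 with set 3, and with it each difference below, was chosen after the result was seen, while the tests of gene length, matched genes, scaling and sample splits were set before their results.

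The sets differed from each other in 8097 genes by the edgeR quasi-likelihood test. 7 of 29 lists differed by camera and 0 with an estimated correlation. The median of set 3 minus set 2 on the log2 scale was 0.35 for G1/S and DNA replication genes, 0.39 for YAP/TAZ targets, 0.30 for nuclear oxidative phosphorylation genes and 0.18 for glycolysis genes. It was -0.28 for apoptosis genes and -0.30 for interferon response genes, of which 24 of 43 were lower in set 3 and 4 higher. The estimated-correlation adjusted p was 0.513 for the G1/S, apoptosis and interferon lists, 0.773 for the glycolysis and YAP/TAZ lists and 0.830 for oxidative phosphorylation. Among named genes that moved in opposite directions, the difference was 1.36 for MYC, 1.27 for RPL19, 1.00 for PFKM, the muscle phosphofructokinase, 0.49 for TGFBR1 and -0.95 for VEGFA.

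All 76 ribosomal protein genes were higher in set 3 than in set 2, by a median of 0.67 on the log2 scale. 3 technical causes were weighed, and each test left the difference above 2 SD of the library spread (0.225) or beyond its matched lists. With the trend on gene length removed it was 0.61, and over the scalings run its lowest value was 0.54. The highest of 10000 lists matched on length and expression reached 0.46, with a median of 0.26, so that short, abundant transcripts as a class could account for part of it. Each matched gene was drawn from the 30 nearest other genes, without a limit on their distance. Drawn singly, these genes need not share the correlation of the ribosomal list (estimated at 0.685). Whether the class could account for all of the difference therefore cannot be decided by this test. Log2 expression of the sets correlated at 0.987 to 0.988 between them, as between set 2 and puro, against 0.998 to 0.999 within a set. These values argue against the 2 sets being plain repeats of the same material. What the first number of the column names marks, and whether it lies behind the ribosomal difference, stays open and was not tested, since no label says it.

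The 10 ways of splitting each set of 6 libraries are too few for a share under 0.05. The real split of puro and knockdown samples gave 7842 genes and the highest other split 0 by edgeR (8374 and 218 at an unadjusted p under 0.05), the real split being the 1 that gave as many. For set 2 the counts were 8333 and 0 (8754 and 113), for set 3 they were 7135 and 0 (7693 and 452), and between the sets 8042 and 0 (8499 and 198).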

How the results depend on the processing

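The settings that use 1 column set, read the first number as the sample number, or leave out genes with a site were chosen after the data were seen. IGF2BP2 was lower in all 24 alternatives, between -1.68 and -1.19. Leaving out 1 library gave 6889 to 8028 changed genes and 5 to 6 lists, 7134 to 7927 genes in set 2 and 6482 to 7506 in set 3. A minimum log2 fold change of 1, a stricter criterion by construction, left 1011 genes (525 higher, 486 lower), 35 named genes, 1483 in set 2, 1247 in set 3, 449 in the same and 19 in opposite directions in both sets, and 1520 between the sets; it gave no list value. At FDR 0.01, 757 genes were opposite in the sets. With the first number as sample number, which leaves fewer samples, 1285 genes passed (715 higher, 570 lower), with 44 named genes. Without genes that hold a site or were not searched, fewer genes were tested: 3979 passed (2015 higher, 1964 lower), with 31 named genes; genes changed in set 2 numbered 4166, genes changed in set 3 numbered 3767, 1917 were in the same and 600 in opposite directions, and genes that differ between the sets numbered 4182. Lists shifted numbered 0 with an estimated correlation (2 at an unadjusted p under 0.05), 17 by fry and 29 by fry for either direction, which do not compare a list with other genes. With set 2 only, PFKM (-0.19), TGFBR1 (-0.21) and MYC (-0.39) reversed; with set 3 only, IGF2BP3 (-0.061), SLC16A1 (-0.12), CCND1 (-0.022), RPL19 (0.16), VEGFA (-0.39) and the ribosomal protein median (0.27) did; the cause was not tested. With a replicate block 7302 genes passed (genes higher after IGF2BP2 knockdown 3637, genes lower after IGF2BP2 knockdown 3665), with 5 lists and IGF2BP2 at -1.43. The block changed no other count of calls by over 1.5 times. Deviations of same-numbered puro and summed knockdown samples correlated at -0.04, -0.06 and 0.01 across genes. These values gave no sign that the numbers pair the samples. They cannot exclude it, since the sums assume that same-numbered columns belong together. DESeq2 gave 7627 genes and limma-voom 7861. Depth limits calls for genes near the floor, such as IGF2BP1.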

Other observations

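The word scan, its site tests and the tests of shared puro values, leukocyte loss and puro state were chosen after the results they bear on were seen, while the test of sites in NF-kB targets was set before its result.

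Among lists not described above, YAP/TAZ targets showed 14 rises and 6 falls in 23 genes (14 and 6 adjusted over the list alone; camera adjusted p = 0.189), with ASAP1, an Arf GTPase-activating protein, at 1.29 and F3, which encodes tissue factor, at -0.75. In set 3 alone this list was higher (camera adjusted p = 0.0184, adjusted p = 0.599 with an estimated correlation). Over all samples the YAP/TAZ list stayed uncalled in 20 of 27 alternatives. Epithelial genes showed 6 rises and 13 falls in 27 (6 and 13 adjusted over the list alone; camera adjusted p = 0.256), and mesenchymal genes 11 and 10 in 29 (11 and 10; camera adjusted p = 0.876). Renal tubule genes showed 3 rises and 6 falls in 13 (3 and 6 adjusted over the list alone; camera adjusted p = 0.189). Of 25 proposed IGF2BP2 mRNA targets, 13 rose and 8 fell (14 and 8 adjusted over the list alone; camera adjusted p = 0.356).

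Each group of columns had its own leading 7-base word in 3' UTRs among 15958 words. Genes with GTCATCA were lower in set 2 (log2 effect -0.34, t = -16.7, 1246 genes), and genes with GGGAAAT were lower in set 3 (-0.24, t = -14.7, 2094 genes). Genes with ACACATC were higher in both sets (0.24, t = 14.1, 1286 genes). The largest absolute t in 100 permutations was 5.22, 5.30 and 5.10. In each case the word of second rank was the first shifted by 1 base and ending in A. In 20 random splits of the genes into equal parts, GTCATCA and GGGAAAT were each picked in 1 part and ranked 1 in the other part all 20 times. ACACATC was picked 13 times and then ranked 1 in the other part 6 times and 2 in 7, and CACATCA was picked 7 times and ranked 2 in 5 and 3 in 2. A site of the GTCATCA kind was present in 28.8% of genes that fell at least 2-fold in set 2 against 16.2% of others, and one of the GGGAAAT kind in 42.2% against 26.5% for set 3. One of the ACACATC kind was present in 85 of 184 genes that rose at least 2-fold in both sets (46.2%, exact 95% interval 38.8 to 53.7%) against 16.7% of 12510 others, and with the word of second rank and its A form the shares were 37.5% and 17.7%. These shares are on the genes the words were picked on, so no p is given, and they are not adjusted for UTR length.

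In the part of the genes it was not picked in, over 20 random splits, the leading word was held by 26.5 to 40.0% of rises of at least 2-fold in both sets and by 8.93 to 12.2% of other genes, with a lowest ratio of 2.31. A candidate explanation for part of these rises is a small RNA in the puro cells that holds genes with the word down, as the seed of a hairpin could, but hairpin sequences are not given in the sources used here, and it would not cover the differences between the sets in rises such as those of PEG10 and TMEM45A. The same reading would apply to the knockdown columns, for GTCATCA in set 2 and GGGAAAT in set 3, and was not tested either. ACACATC was picked on the mean of both sets over puro. A response to loss of IGF2BP2 in genes with this word would thus give the same shares. These values cannot tell such a response from a small RNA in the puro cells. GTCATCA, GGGAAAT and ACACATC occur 1, 2 and 1 times in the longest IGF2BP2 transcript, so their presence there does not tell the groups of columns apart. Of the smaller rises in both sets 28.1% had a site (interval 26.0 to 30.3%) against 15.3% of others, more than others but too few for a site as the main cause of them all. Spread between the puro columns as the whole cause of the rises of at least 2-fold is argued against by their number. There were 209 such rises at an unadjusted p under 0.05 by edgeR in both sets, against at most 7 simulated. The covariance was 0.239 (highest simulated 0.0177), but it covers all genes and not these rises. A shift shared by all 3 puro columns was not simulated, so these values cannot decide on it. Such a shift, a part of the smaller shared rises from the puro libraries, and loss of IGF2BP2 stay open and were not tested.

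NF-kB targets and cytokines were lower in both sets. Members without a site of the set 2 or set 3 kind, 21 of 33 searched, had medians of -0.96 and -0.62, which argues against such sites as the cause. In the puro libraries, the leukocyte genes PTPRC, LYZ, TYROBP and CD52 together held 0.00243% of the 1502 CPM the NF-kB list lost. Only these genes, from a list of 26 leukocyte markers, entered this test. Another marker on that list, SRGN, averaged 31.9 CPM over all samples. The share thus depends on the markers taken, and it cannot decide on a loss of leukocytes. A state of the puro cells unrelated to the knockdown may also lower the 23 members in both sets and cannot be told apart from the knockdown, because both sets share the same puro libraries.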
